A study of Mus musculus with 2 samples.

How the data were processed

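Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map histone H3 trimethylated at lysine 9 (H3K9me3), a mark of silenced chromatin. The tissue was forebrain of mixed-sex B6NCrl mouse embryos at day 15.5 of development. There was 1 group with 2 biological replicates, each a separate pool of embryos: 78 embryos for replicate 1 and 62 for replicate 2. Replicate 1 joined 2 technical replicates and replicate 2 had 1. Per the labels, fragments of 300 to 500 bp were selected. No treated, mutant or other-tissue group was in the series, so every comparison was between the replicates, between peak lists, or between peaks and the same peaks moved along their chromosomes.

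The authors aligned reads to the mouse build mm10 and called peaks against control alignments, which were not analysed here. They deposited 4 peak lists: replicate 1 alone, replicate 2 alone, both replicates pooled, and a replicated list derived from the other 3. The peak caller, its threshold and the rule behind the replicated list were not given in the sources used here. Each deposited peak carried a signal value, which stands for enrichment over control on a scale that the labels do not state. It also carried the caller's −log10 p and −log10 q, both in the units deposited by the authors. The last deposited column, of another kind of unit, gave the summit as an offset in bases from the peak start. The sequencing depth was not given in the sources used here, so no limit from read counts could be set, and signal values were used only within a list, to rank peaks or to describe named ones. Intervals on shares of peaks are exact 95% binomial intervals (Clopper-Pearson). They cover counting error only, and neighbouring peaks are not independent.

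Coordinates were compared with the GRCm38 genome sequence and GENCODE release M21, and 0 peaks of any list lay past a chromosome end. Comparisons used chromosomes 1 to 19, X and Y, or the same without Y for sequence composition. Peaks on unplaced or unlocalised contigs were left out of them because those contigs have no position to shift along. Gene symbols and coordinates come from GENCODE M21, with 21938 protein-coding genes.

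Replicate peaks counted as shared when they overlapped by at least 50% of either peak. The background was 100 circular shifts, in which the peaks of a chromosome were moved together by a random offset between the first and the last pooled peak. This circular-shift permutation test was 2-sided, and 0.0198 is the smallest p it can give with 100 shifts. The Jaccard index is the base pairs covered by both lists over the base pairs covered by either. For gene lists, a gene was counted when at least 1 bp of peak lay in its body or 2 kb upstream, and 10000 circular shifts of the replicated peaks gave the background. With 10000 shifts the smallest 2-sided p is 0.0002. Values of p were adjusted by the Benjamini-Hochberg method over 22 lists, with 0.05 as the threshold. The lists were numbered zinc finger (Zfp), SCAN zinc finger, olfactory receptor, vomeronasal receptor, clustered protocadherin, keratin, defensin, cytochrome P450, UDP-glucuronosyltransferase and sulfotransferase, serpin, Prame-like and Speer, X-linked germline, replication-dependent histone, Hox, ribosomal protein, imprinted, forebrain transcription factor, neuronal, glial and progenitor, non-neural lineage, germline, and H3K9 methylation machinery genes.

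Peak base pairs were assigned to promoters (2 kb upstream to 500 bp downstream of a transcription start site, TSS), exons, introns or sequence outside protein-coding genes, with 100 shifts and adjustment over the 4 classes. For the position inside Zfp genes, the covered bases of each gene were rotated at random along the gene body 10000 times, in a 1-sided test whose smallest p is 0.0001. Imprinted genes of any gene type were also tested within 2 kb of a TSS. Domains joined replicated peaks at most 10 kb apart, and uniform placement of the peaks 20 times gave a comparison. GC content, the observed over expected CpG ratio and the soft-masked (repeat) share were compared with 100 shifts, without chromosome Y, and adjusted over 3 measures. Repeated sequence was gauged by 31-base words. A peak counted as made of once-found words when at least 90% of its words occurred once, on either strand, among 65 primary sequences of the genome.

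The tests, the gene lists, most alternatives and the naming rule were set before the data were examined. The rule named, from each list, up to 4 genes with the largest covered share of the gene body among those with a peak in both replicates, or all members where 5 or fewer had a peak. It also named the 10 genes outside the lists with the most covered base pairs, up to 3 genes in each of the 10 longest domains, and the gene nearest to each of the 10 replicated peaks of highest signal value. Genes on chromosomes 18 and Y were counted but not named, so the ranking by signal value skips peaks there. Genes named outside the rule are said to be so.

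The alternatives set in advance were the pooled list, each replicate's list alone, the upper 50% of peaks by q value, other overlap minimums, lists cut to equal length, at least 200 bp covered, windows around the TSS, length-matched gene lists in 20 length bins, list genes within 200 kb counted once, other promoter windows, and domain gaps of 5 and 25 kb. Chosen after seeing the data were peaks made of once-found words, leaving out the 5% of peaks with the highest −log10 p for their signal value, and leaving out chromosome 7. So were the scan of gene families, the genes in large domains, the check of other long last exons and the checks of the X chromosome. The length-matched comparison drew genes singly within length bins, so, unlike the shifts, it ignores the tandem clustering of genes. No paired or between-group test applies with 1 group.

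The list test was tested on simulated data, with 1000 shifts in place of 10000 and 20 simulations. With shifted peaks and no effect, 2 of 440 lists were called, and with 500 bp peaks given to 30% of the genes of 4 lists, 76 of 80 were recovered, while 5 of 360 other lists were called beside them. The rotation test called 0 of 20 random and 20 of 20 planted placements. The no-effect peaks were placed by the same kind of random move as the background of each test. Their rates therefore check the computation, and cannot show how the tests behave with the spread of real peaks. The overlap counts equalled those of bedtools 2.31.1 in 3 of 3 settings, and 3900 of 3900 word counts equalled a direct count. Computation used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.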

Results

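H3K9me3 was mapped by ChIP-seq in mouse forebrain at embryonic day 15.5, as part of a catalogue of histone marks in developing tissues. The group held 2 replicates, pools of 78 and 62 embryos of both sexes. Replicate 1 gave 59420 peaks and replicate 2 gave 36710. The pooled list held 59320 peaks with a median width of 244.5 bp, and the replicated list held 15142 with a median of 426 bp. On the chromosomes, the replicated peaks covered 7.71 Mb, against 15.5 Mb for replicate 1 and 9.49 Mb for replicate 2. Sequencing depth was not given in the sources used here. The share of peaks with a q under 0.05 was 32.4% in replicate 1, 36.8% in replicate 2, 67.8% in the pooled list and 96.8% in the replicated list.

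The first comparison asked how far the separately called lists coincide. The replicated peak of highest signal value (11.3) overlapped an exon of Klf14, a zinc finger transcription factor gene, and ran past that exon. The peak lay on chromosome 6 from 30956371 to 30959344 (GRCm38). Outside chromosomes 18 and Y, which held 4 of the 10 highest peaks, the next was intergenic, 63.2 kb from Zfp990 on chromosome 4, with a signal of 9.56. A pair of peaks in Zfp981 followed, with signals of 7.90 in an exon and 7.83 in an intron. Peaks in Zfp978 and Zfp810 had signals of 7.49 and 7.32, an intronic peak of D130040H23Rik had 7.69, and a peak 12.98 kb from Ptchd3 had 7.28. A pair of intergenic peaks on chromosome 16, 323 and 348 kb from the olfactory receptor gene Olfr161, had 7.57 and 7.20. Each of these peaks was overlapped by a peak in both replicates.

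Of the 59009 replicate 1 peaks on chromosomes, 9686 (16.4%, exact 95% interval 16.1 to 16.7%) were shared with replicate 2. Of the 36327 replicate 2 peaks, 9831 (27.1%, 26.6 to 27.5%) were shared with replicate 1. Shifted peaks gave 0.557% and 0.905%, so sharing was 29.5 and 29.9 times the shifted level (circular-shift permutation, p = 0.0198 for each, the smallest 100 shifts can give). The Jaccard index was 12.1%, which was 41.6 times its shifted level of 0.292% (permutation p = 0.0198). In the decile of highest signal value, 41.6% of replicate 1 peaks and 53.2% of replicate 2 peaks were shared, against 9.39% and 21.8% in the lowest. The lowest shares, 7.41% and 17.1%, were in the eighth decile of each list. When the overlap had to reach 50% of both peaks, the shares were 10.05% and 16.3%.

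**Figure D1:**
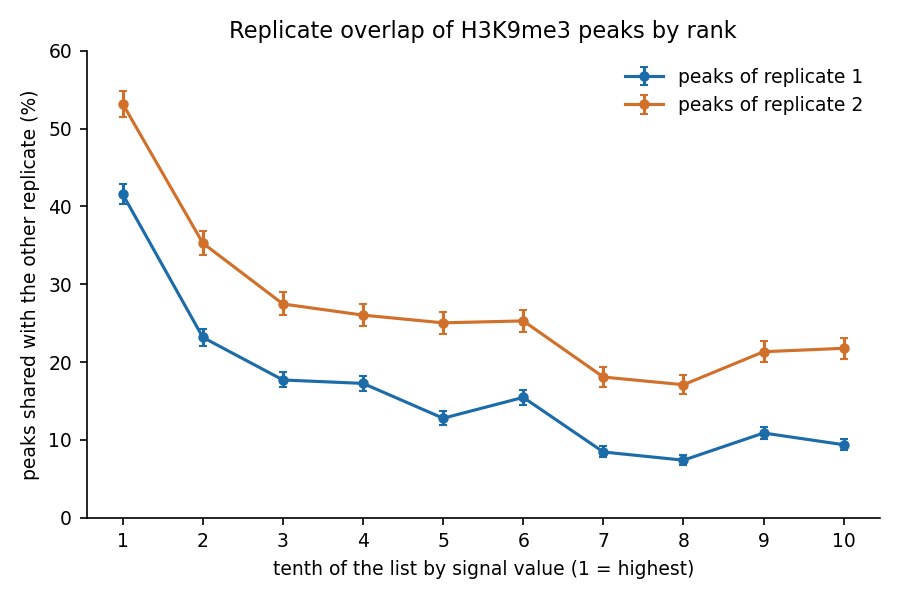
Percent of peaks shared with the other replicate (vertical axis) by decile of signal value within each list (horizontal axis, highest first), with exact 95% intervals as bars. Sharing is highest in the first decile, 41.6% for replicate 1 and 53.2% for replicate 2, and lowest in the eighth, 7.41% and 17.1%.

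The replicated list was a subset of the pooled list. All 15142 replicated peaks had the coordinates of a pooled peak, and they made up 25.5% of the pooled peaks (25.2 to 25.9%). Of the 14886 on chromosomes, 91.3% were overlapped by replicate 1, 85.9% by replicate 2, 77.6% by both and 69 peaks by neither. The 11555 pooled peaks overlapped by both replicates were all in the replicated list. Among pooled peaks in the decile of highest signal value, 86.8% were kept, and among those in the lowest decile 4.07%. Among the upper 50% of pooled peaks by q value, 45.9% were kept.

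The next question was which genes carried the mark. Replicated peaks lay in or just upstream of 1792 of 21938 protein-coding genes (8.17%). Numbered Zfp genes, a family whose products include many repressors of transposable elements, carried one in 31.2% of 394 cases, 3.44 times the shifted mean (adjusted permutation p = 0.0022). In Zfp110 on chromosome 7 (12834761 to 12850577), peaks covered 82.5% of the gene body. Coverage was 81.7% in Zfp873 on chromosome 10, 72.0% in Zfp68 on chromosome 5 and 67.8% in Zfp2 on chromosome 11. In the replicates' own lists, 42.8% ± 3.41 (SD, n = 2) of the Zfp genes had a peak. The fold over shifted was lower there, 1.57 with replicate 1 alone and 1.88 with replicate 2 alone.

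Vomeronasal receptor genes, which encode pheromone receptors, carried a replicated peak in 95 of 327 cases, 3.67 times the shifted mean (adjusted permutation p = 0.00293). The most covered were Vmn1r65 (54.0%), Vmn1r66 (37.5%), Vmn1r71 (31.1%) and Vmn1r171 (23.9%), all on chromosome 7. In the replicates' own lists, 41.4% ± 6.70 (SD, n = 2) of these genes had a peak, with folds of 2.02 for replicate 1 and 2.18 for replicate 2. Clustered protocadherin genes, which encode neuronal adhesion molecules expressed in cell-specific combinations, carried one in 53 of 57 cases, 5.87 times the shifted mean (adjusted permutation p = 0.0044). The count was 53 in each replicate as well, but the fold over shifted was lower, 1.94 with replicate 1 alone and 2.24 with replicate 2 alone.

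Imprinted genes, expressed from a single parental allele, carried a replicated peak in 27 of 41 cases, 4.88 times the shifted mean (adjusted permutation p = 0.0022). The most covered were Nap1l5 (38.8%), Zrsr1 (30.8%), Nnat (13.8%) and Blcap (13.8%). In the replicates' own lists, 75.6% ± 3.45 (SD, n = 2) of imprinted genes had a peak, with folds of 1.86 for replicate 1 and 2.49 for replicate 2. UDP-glucuronosyltransferase and sulfotransferase genes, which encode liver conjugating enzymes, carried one in 17 of 42 cases, 3.85 times the shifted mean (adjusted permutation p = 0.0352). Peaks covered 93.6% of Ugt1a1, whose enzyme conjugates bilirubin, 43.6% of Ugt1a2, 16.2% of Sult2a8 and 16.0% of Ugt1a5. The 9 Ugt1a genes share their 3′ exons, so a single peak counted for several of the 17.

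These were the 5 of 22 lists above the shifted level after adjustment, and 0 lists lay below it in this circular-shift test. At an unadjusted p under 0.05, 6 were above and 0 below. A list could fall below at that level only if shifts rarely left it with 0 genes with a peak. This held only for the Zfp, olfactory receptor, vomeronasal, cytochrome P450, imprinted and neuronal lists. For the other lists, the test with replicated peaks could not have shown a deficit. The calls differed in how they held when genes were grouped: with list genes within 200 kb counted once, Zfp genes (65 of 201 loci, 2.52-fold, adjusted permutation p = 0.0022) and imprinted genes (17 of 23 loci, 3.71-fold, adjusted p = 0.0022) stayed above the shifted level. Vomeronasal genes (19 of 47 loci, 1.54-fold, adjusted permutation p = 0.422) and conjugating enzymes (2 of 12 loci, 0.946-fold, adjusted p = 1) did not. The protocadherin genes form a single locus, for which this count cannot pass a test. The conjugating enzymes also lost their call with the pooled list (1.48-fold), replicate 1 alone (1.38-fold), replicate 2 alone (1.91-fold), windows around the TSS (4.69-fold), without chromosome 7 (3.40-fold) and without the peaks of highest p for their signal (3.68-fold, adjusted permutation p = 0.0546). Around the TSS, 15 Zfp genes carried a peak, 1.31 times the shifted mean (adjusted permutation p = 1). Over the 11 alternatives the fold ran from 1.31 to 4.67 for Zfp genes, from 1.54 to 6.11 for vomeronasal genes, from 1.51 (the single locus) to 51.8 for protocadherins and from 1.86 to 9.40 for imprinted genes, with the replicates' own lists among the lower values.

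**Figure D2:**
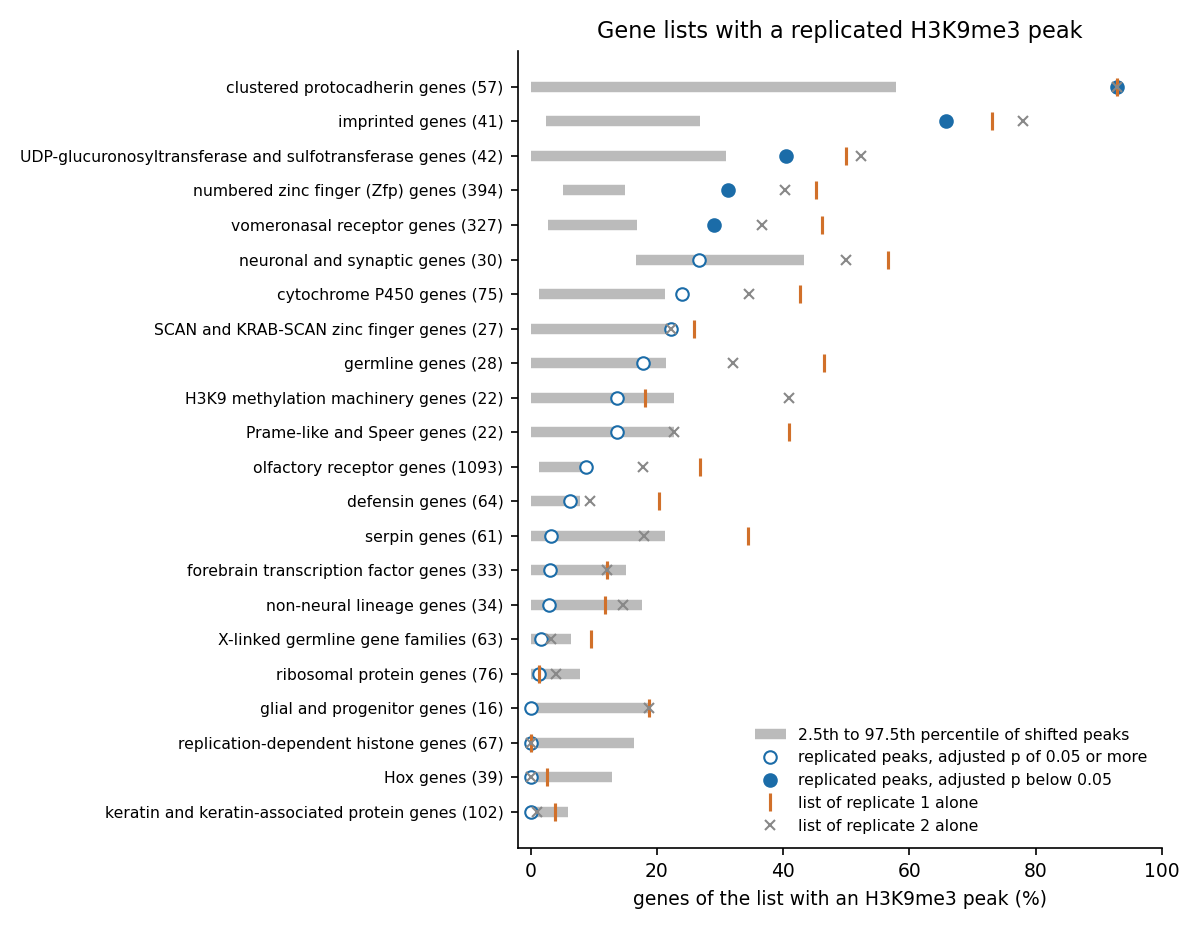
Percent of the genes of each of the 22 lists with a peak (horizontal axis), for the replicated list and for each replicate, with grey bars for the central 95% of 10000 shifts of the replicated peaks. The replicated value lies beyond the grey bar for the 5 called lists, such as imprinted genes at 65.9% and Zfp genes at 31.2%, and also for cytochrome P450 genes at 24.0%, which did not pass after adjustment; no shifted range is drawn for the replicates' own lists.

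Other tandem families did not pass the test with the replicated list. Olfactory receptor genes carried a peak in 96 of 1093 cases (2.31-fold, adjusted permutation p = 0.166), with the largest covered shares in Olfr866 (82.3%), Olfr356 (56.6%), Olfr854 (31.9%) and Olfr398 (31.6%). This list was called with the pooled list (1.92-fold), each replicate alone (2.15 and 2.04-fold), length-matched lists (2.26-fold), once-found words (2.86-fold) and without chromosome 7 (3.90-fold, adjusted permutation p = 0.0044), but not with list genes within 200 kb counted once (15 of 62 loci, 1.13-fold, adjusted p = 1). Cytochrome P450 genes, many of them liver enzymes of drug and steroid metabolism, had 18 of 75 (2.75-fold, adjusted permutation p = 0.114), with 16.7% of Cyp3a11, 14.8% of Cyp3a16, 12.3% of Cyp2b9 and 11.4% of Cyp2c29 covered. They were called with the pooled list (1.76-fold, adjusted permutation p = 0.0374) and length-matched lists (4.07-fold). SCAN zinc finger genes had 6 of 27 (3.09-fold, adjusted permutation p = 0.222), the most covered being Zkscan7 (7.44%), Zscan5b (3.15%), Zkscan3 (3.03%) and Zkscan8 (2.21%). They were called with length-matched lists (4.64-fold), and their fold was 0.837 with the upper 50% of peaks and 0 around the TSS. Length matching drew genes singly and ignored their clustering, so its calls for the olfactory, cytochrome P450 and SCAN lists may come too easily. With loci counted once, neither cytochrome P450 genes (7 of 21 loci, 1.82-fold, adjusted permutation p = 0.581) nor SCAN genes (5 of 15 loci, 3.15-fold, adjusted permutation p = 0.261) passed. Defensin genes, which encode antimicrobial peptides, had 4 of 64 (4.35-fold, adjusted permutation p = 0.226): Defb33, with 29.6% covered, Defb8, with 22.3%, and Defb4 and Defb14, whose peaks lay upstream. Prame-like and Speer genes had 3 of 22 (4.14-fold, adjusted permutation p = 0.283), namely Pramef12, Pramef20 and Pramel4, and were called with the pooled list (4.73-fold, adjusted p = 0.0169). Serpin genes had 2 of 61 (0.617-fold, adjusted permutation p = 1), Serpinb6d with 30.3% covered and Serpina6, which had no peak in replicate 2, and the fold was above 1 with the pooled list (1.53) and in each replicate alone (1.49 and 1.15).

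None of the lists of brain and lineage genes differed from the shifted level. Except for the neuronal list, a deficit could not have been shown, since shifts too often left 0 genes with a peak. Forebrain transcription factor genes had 1 of 33 (0.441-fold, adjusted permutation p = 0.916), a peak of 590 bp in Cux1. Neuronal genes had 8 of 30 (0.911-fold, adjusted permutation p = 1), and the covered share was small in each of those named: 0.665% of Snap25, a component of synaptic vesicle fusion, 0.350% of Reln, 0.235% of Grin2b, an NMDA receptor subunit, and 0.234% of Cacna1a. Glial and progenitor genes had 0 of 16 (adjusted permutation p = 0.916). Non-neural lineage genes had 1 of 34 (0.366-fold, adjusted permutation p = 0.799), in Trp63, a regulator of epidermis. The neuronal and non-neural folds were above 1 with the pooled list (1.04 and 1.12).

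Germline genes had 5 of 28 (1.75-fold, adjusted permutation p = 0.598). Nlrp5, a maternal-effect gene of the oocyte, held 31 peaks over 32.3% of its body, while Ddx4, Dazl and Dmrt1, genes of germ cell development, held 1 peak each. The fifth was Rpl10l, a testis-expressed ribosomal protein gene with no peak in replicate 1. Around the TSS the germline list was above the shifted level (4 genes, 7.88-fold, adjusted permutation p = 0.0154). H3K9 methylation machinery genes had 3 of 22 (1.33-fold, adjusted permutation p = 1): Atf7ip, a partner of the methyltransferase SETDB1, and Morc2a and Fam208a, of the HUSH silencing pathway. Their fold fell below 1 with the pooled list (0.617), replicate 1 alone (0.444) and around the TSS (0). Ribosomal protein genes had 1 of 76 (0.418-fold, adjusted permutation p = 0.916), Rpl10l again, and were below the shifted level with the pooled list (0.139-fold, adjusted p = 0.0270) and replicate 1 alone (0.128-fold, adjusted p = 0.0176). The X-linked germline list, whose pattern also took in the autosomal Mageb3 and Slx4, had 1 of 63 (0.996-fold, adjusted permutation p = 1), in Rhox13, with no peak in replicate 2. No replicated peak was found for histone (0 of 67, adjusted permutation p = 1), Hox (0 of 39, adjusted p = 1) or keratin genes (0 of 102, adjusted p = 0.916).

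Outside the lists, the most covered bases were in Skint5 on chromosome 4, a member of a family of immunoglobulin-like genes of skin and thymus, with 144 peaks over 68795 bp. Its neighbours Skint6 and Skint2 had 125 and 32 peaks. Mroh2a and Trpm8, the latter a cold-sensing channel gene, lie next to the Ugt1a genes on chromosome 1, and had 81.8% and 20.4% of their bodies covered. Gm4924 and AU041133, near Zfp873 on chromosome 10, had 29.3% and 63.2% covered. D130040H23Rik on chromosome 8 had 41.0%, and Ceacam5 and Nlrp2 on chromosome 7 had 29.9% and 26.1%. All 10 genes had a peak in both replicates. They were ranked by covered base pairs without a test of each gene.

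Within Zfp genes, the question was whether the mark lay at the 3′ end, where the zinc finger exon is found. Of the replicated base pairs in 121 Zfp genes, 36.7% lay in the last exon, against 16.1% after rotation, a 2.27-fold difference (permutation p = 0.0001, the smallest 10000 rotations can give). The final stretch of the gene body, 33.3% of its length, held 59.5% of them, 1.79 times the rotated share (permutation p = 0.0001). A peak reached the last exon in 94 of the genes. In the replicates' own lists, the last-exon share was 34.9% ± 1.75 (SD, n = 2) and the share of the final stretch 57.5% ± 1.38 (SD, n = 2). In other protein-coding genes with covered bases, 1440 in number, 4.55% of covered base pairs lay in the last exon, 1.11 times the rotated share of 4.08% (permutation p = 0.0297 with 100 rotations). Their final stretch held 25.3%, 0.761 times the rotated share. Overlapping genes each counted the bases they shared, so these other genes are not independent. Genes were set apart by symbol, so zinc finger genes without a numbered Zfp symbol counted as other genes.

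**Figure D3:**
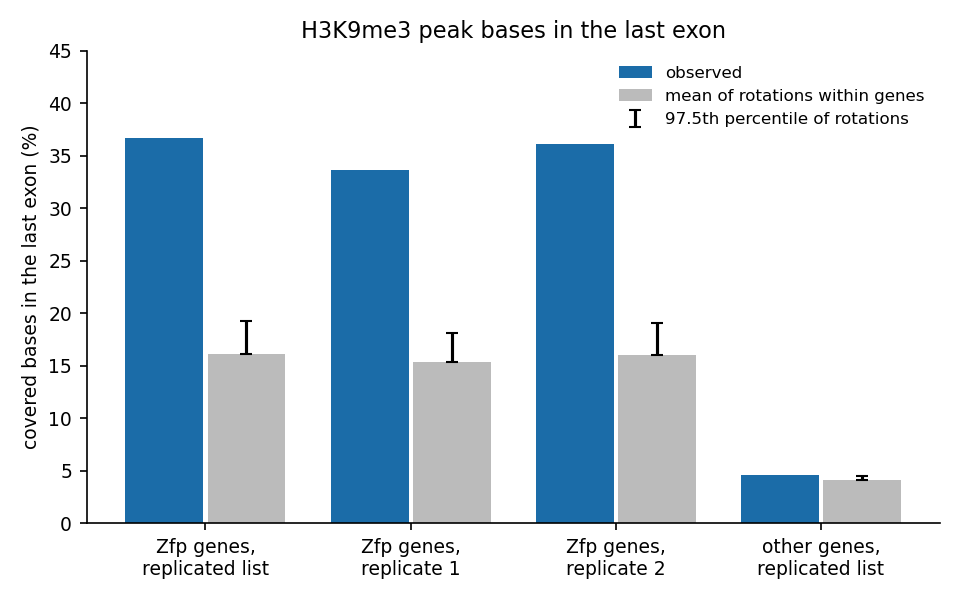
Percent of covered base pairs that lie in the last exon of the gene (vertical axis) for Zfp genes in the replicated list and each replicate, and for other protein-coding genes in the replicated list (blue bars), beside the mean after rotation (grey bars, with whiskers to the upper end of the central 95%). Zfp values are 36.7%, 33.7% and 36.2% against rotated means of 16.1%, 15.4% and 16.0%, and other genes are at 4.55% against 4.08%.

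At imprinted loci, the mark was counted around promoters. Of 47 imprinted genes of any type, 25 had a replicated peak within 2 kb of a TSS, 10.2 times the shifted mean (permutation p = 0.0002, the smallest 10000 shifts can give). The replicates' own lists gave 27 and 28 genes, or 58.5% ± 1.504 (SD, n = 2). The genes below were named after their values were seen. The highest signals were 5.74 at Grb10, an adaptor of growth factor receptors (chromosome 11, 12025202 to 12026878, overlapping an exon), and 5.51 at Mest (chromosome 6, 30737915 to 30738428). Peg3 and Usp29 shared an intronic peak with a signal of 4.63, Herc3 and Nap1l5 one of 4.42, and Gnas and the antisense Nespas one of 4.37. Signals were 4.30 at Plagl1, 4.16 at Snrpn and Snurf, 4.04 at Nnat and Blcap, 4.01 at Inpp5f, 3.85 at Airn and 3.74 at the noncoding Meg3. The strongest peaks of the 25 genes were 18 distinct peaks on 9 chromosomes, and the peak at Mcts2 was missing from replicate 1. The fold was 3.69 with replicate 1 alone and 5.35 with replicate 2 alone, whose shifted counts were higher.

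Across annotated classes, exons lay above the shifted level and introns below it. Exons held 5.88% of replicated base pairs, 2.19 times the shifted mean (adjusted permutation p = 0.0396), and 4.13% ± 0.422 (SD, n = 2) of the base pairs in the replicates' own lists. Introns held 23.8%, 0.653 times the shifted mean (adjusted permutation p = 0.0396), and 24.4% ± 1.28 (SD, n = 2) in the replicates. Sequence outside protein-coding genes held 65.8% (1.15-fold, adjusted permutation p = 0.0528), and promoters 4.54% (1.29-fold, adjusted p = 0.0792). Outside sequence passed the test with the pooled list and with each replicate alone (1.16 to 1.20-fold, adjusted permutation p = 0.0264 for each). Promoters passed it with the upper 50% of peaks (1.505-fold) and lay at 0.975 of the shifted level with replicate 1 alone.

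Replicated peaks gathered in long domains. The longest, on chromosome 7 from 17884434 to 18187189, spanned 303 kb with 141 peaks and held Ceacam12, Ceacam13 and Gm5155, and another of 235 kb nearby held Ceacam5 and Ceacam14. On chromosome 13, domains of 265 and 197 kb held the cathepsin genes Ctsm and Cts3, and Cts6 and Cts8, proteases of the placenta, beside Gm49352 and Gm49398. On chromosome 4, domains lay over Gm12887 (250 kb), across the start of Skint5 and upstream of it (210 kb), and over Zfp978, Zfp982 and Zfp985 (196 kb). A domain of 193 kb on chromosome 7 held Vmn1r66. Domains of 236 kb on chromosome 12 and 203 kb on chromosome 6 held no protein-coding gene. Genes of other annotated types were not counted, so these domains need not be empty of genes.

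Joining peaks at most 10 kb apart gave 5439 domains, of which 259 held 10 or more peaks. Those 259 took up 6741 peaks (45.3%), and 26.4% of peaks stood alone. With the same peaks placed uniformly, 81.9% stood alone and no domain held more than 8. Replicate 1 alone gave 502 domains of 10 or more peaks and replicate 2 alone gave 408.

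Chromosome 7 had the highest density, 20.6 replicated peaks per Mb, followed by chromosome 17 with 15.4 and chromosome 4 with 10.8. The X chromosome had 1.27 per Mb. Chromosome 7 stood at 4.08 times the density of the other autosomes, and at 2.81 and 2.91 times with replicate 1 and replicate 2 alone. Over the autosomes, replicate 1 had 1.42 to 1.78 times as many peaks as replicate 2, and on X it had 2970 against 1070, or 2.78 times. Of the X peaks of replicate 1, 4.28% were shared with replicate 2. The X density was 0.213 of the autosomal one with the replicated list, 0.437 with replicate 2 alone and 0.763 with replicate 1 alone.

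**Figure D4:**
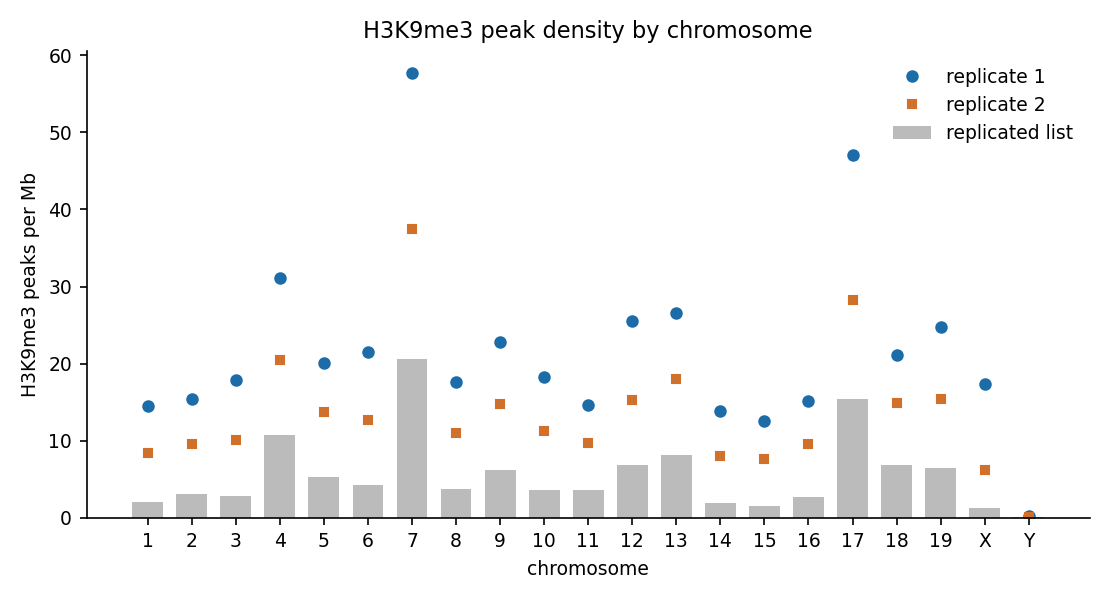
Peaks per Mb on each chromosome (vertical axis) for the replicated list and for each replicate. Chromosome 7 is highest in all 3 lists, with 20.6 per Mb in the replicated list, and X has 17.4 per Mb in replicate 1 against 6.26 in replicate 2.

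The sequence under replicated peaks had a lower CpG ratio than that under any of the 100 sets of shifted peaks. The observed over expected CpG ratio was 0.159 against a shifted mean of 0.193 (range 0.184 to 0.203), or 0.825-fold, and 0.155 ± 0.00545 (SD, n = 2) in the replicates. Its permutation p of 0.0198 is the smallest that 100 shifts can give, and adjustment over 3 measures cannot bring a lone measure below the 0.0594 found, so the adjusted test could not have passed for it alone. GC content was 42.9% against 42.2% (adjusted permutation p = 0.0891). Soft-masked sequence made up 32.8% against 34.0% (adjusted permutation p = 0.297). GC content and the CpG ratio passed the test with the pooled list and with replicate 2 alone, where both were at the smallest p (adjusted permutation p = 0.0297 for each), and the soft-masked share lay above the shifted level with the pooled list (1.02-fold) and replicate 1 alone (1.03-fold).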

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

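No test in this part was chosen after the result was seen. The replicated list held 256 peaks on 22 unplaced or unlocalised contigs, which no comparison used, so they stand out as signal outside the main measurement. They were 1.69% of the list and covered 236 kb, and 72 of them lay on a single contig, JH584304. Replicate 1 had 411 contig peaks and replicate 2 had 383. No control samples were analysed here, and no technical or biological explanation was tested.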

How the results depend on the processing

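Peaks of once-found words, leaving out peaks of highest p for their signal, and leaving out chromosome 7 were chosen after the results were seen. Of 95 alternative values for the main results, 70 counted as unchanged: tested values that kept direction and side of the threshold, counts and overlap shares within 1.5 times the main value, and other values within 1 SD of the replicates. That margin is wide: it takes in 4 to 7 lists above the shifted level, 183 domains with a gap of 25 kb, an X ratio of 0.431 with the pooled list, and 2 values from merging touching peaks. Of 242 values for single gene lists, 202 were unchanged. The last-exon fold stayed between 2.07 and 2.48 (permutation p = 0.0001 in 5 alternatives), the final-stretch fold between 1.67 and 1.92, and the imprinted TSS fold between 3.69 and 13.7 (p = 0.0002 in 6). Exons and introns kept their calls in 5 alternatives each. Merging touching peaks changed nothing, since no peaks of a list overlap, and says nothing about stability. Depth was not given in the sources used here, so its effect could not be gauged.

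The remaining changes were as follows, and the cause was not tested. With an overlap of 50% of both peaks, sharing was 10.05% and 16.3%. The upper 50% of peaks by q value gave 45.9% of pooled peaks kept, a promoter fold of 1.505, a chromosome 7 ratio of 3.96 and a SCAN fold of 0.837. Length-matched lists, which ignore the clustering of genes, gave 8 lists above the background, 5 of them shared with the main 5. Counting nearby genes once gave 2, both shared (the single protocadherin locus cannot pass), a conjugating-enzyme fold of 0.946 and an X-linked germline fold of 1.26. With the pooled list, 1 list lay below the shifted level, outside sequence was at 1.19, the chromosome 7 ratio at 3.11, GC at 1.02, CpG at 0.784, soft-masked sequence at 1.02, serpins at 1.53, neuronal genes at 1.04, non-neural genes at 1.12 and H3K9 machinery at 0.617. The CpG ratio newly passed there and with replicate 2 alone because GC also reached the smallest p, which lowers the adjusted value. Around the TSS, SCAN and H3K9 machinery genes were at 0 and X-linked germline genes at 3.42. X-linked germline genes were at 1.05 with at least 200 bp covered, 1.57 with once-found words and 1.08 without the peaks of highest p. Neuronal genes were at 1.14 with length-matched lists and 1.01 without chromosome 7.

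With each replicate left out in turn, the number of lists below the shifted level was 0 to 1, the promoter fold 0.975 to 1.04, the fold outside genes 1.16 to 1.20, domains of 10 or more peaks 408 to 502, the chromosome 7 ratio 2.81 to 2.91 and the X ratio 0.437 to 0.763. GC was at 1.01 to 1.02, CpG at 0.785 to 0.822, soft-masked sequence at 0.978 to 1.03, serpins at 1.15 to 1.49 and H3K9 machinery at 0.444 to 1.39.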

Other observations

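The tests of large domains, gene families, once-found words, peaks of highest p for their signal, long last exons of other genes and the X chromosome were chosen after the main results were seen. Genes in the 259 domains of 10 or more peaks were compared with shifted domains, with neighbouring domains of a tandem cluster counted separately. A vomeronasal receptor gene lay in 40 of them, 7.32 times the mean of 1000 circular shifts (permutation adjusted p = 0.004). A Zfp gene lay in 32 (6.05-fold, adjusted permutation p = 0.004) and an olfactory receptor gene in 19 (4.38-fold, adjusted p = 0.024). Counted once per locus within 200 kb, neither receptor list stood above the shifted level for all replicated peaks (vomeronasal 1.54-fold, adjusted permutation p = 0.422, and olfactory 1.13-fold, adjusted p = 1), and the olfactory list was not called gene by gene either (adjusted p = 0.166). Any protein-coding gene lay in 169 (1.07-fold, adjusted permutation p = 0.452). Chromosome 7 held 63 of the domains, chromosome 17 held 49 and chromosome 4 held 37.

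Gene families outside the lists were scanned by symbol stem, 616 families of at least 5 genes. After adjustment, 0 were above and 0 below the shifted level in this circular-shift test, with 6 above and 2 below at an unadjusted p under 0.05. A lone family could not have passed, since the smallest permutation p of 0.0002 is too large for adjustment over 616 families. The 6 and 2 are also fewer than a threshold of 0.05 could let through among 616 families with no effect, although not every family could reach it. The folds that follow therefore set no family apart. Nlrp genes, which include maternal-effect genes of the oocyte, carried a replicated peak in 9 of 16 cases (3.65-fold, unadjusted permutation p = 0.0028, adjusted p = 1) at 7 of 13 loci. Klra genes, receptors of natural killer cells, had 7 of 11 (11.7-fold, unadjusted permutation p = 0.0164), Skint genes 9 of 11 at a single locus (3.86-fold, unadjusted p = 0.0348) and Ceacam genes 7 of 15 (4.54-fold, unadjusted p = 0.0428). Taste receptor (Tas) genes had 5 of 38 (8.73-fold, unadjusted permutation p = 0.03), and the sixth stem, the clone names AW, had 3 of 7 (4.14-fold, unadjusted p = 0.029). The stems below were Fam, with 10 of 203 (0.504-fold, unadjusted permutation p = 0.0098), and Tmem, with 9 of 242 (0.496-fold, unadjusted p = 0.0204), both of which gather unrelated genes.

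The concentration of the mark at the last exon of Zfp genes was weighed against reads shared between near-identical copies and against a property of long last exons in general. With only the replicated peaks made of once-found words, the last-exon fold over rotation was 2.28 (95% bootstrap interval over genes 1.95 to 2.67, 90 genes). This argues against reads shared between copies in the assembly as the whole cause. Words were counted in the assembly only, so reads from extra copies missing from it could remain. The fold was not recomputed without the peaks of highest p for their signal. The fold was 1.09 (0.977 to 1.22, 900 genes) in other genes with a last exon of at least 1 kb. In the 1-sided rotation test this small excess passed the threshold (permutation p = 0.049), though its bootstrap interval takes in 1. The fold of 1.09 is below the 2.27 (2.03 to 2.57) of Zfp genes, which argues against exon length alone. Overlapping genes, however, each counted the bases they shared, so the 900 genes are not independent and their interval may be too narrow. Zfp genes were also resampled singly although many lie near each other, so their intervals may be too narrow as well. The repeated zinc finger sequence itself may still contribute, since no other gene set with such repeats was tested. No biological explanation was tested, because the series holds 1 group.

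The peaks over tandem families, with vomeronasal receptor genes as the test case, were weighed against shared reads and against uncounted extra copies. Peaks made of once-found words were 62.3% of replicated peaks and 69.4% of the same peaks in a single shift. The mean share of once-found words went the other way, 89.0% against 83.8%. With peaks of once-found words alone, 76 of 327 vomeronasal genes in place of 95 carried a peak. That was 3.83 times a shifted mean that fell as well (19.8 in place of 25.9). This argues against shared reads as the whole cause. Without the 744 peaks of highest p for their signal, no change in the count of vomeronasal genes was seen (95, adjusted permutation p = 0.00293), so that removal decides nothing and extra copies missing from the assembly could remain. The call rests on neighbouring genes, since loci counted once gave 1.54-fold (adjusted permutation p = 0.422), and no biological explanation was tested.

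Replicate 1 had 2.78 times as many X peaks as replicate 2 (95% interval 2.59 to 2.98), above the highest autosome at 1.78. With replicate 1 cut to as many peaks as replicate 2, the highest by p, the X ratio was 1.28 (1.18 to 1.39) against 1.15 for the highest autosome, which argues against the longer list as the whole cause and leaves room for it as a part. A dosage offset between the pool and its control, with weak calls spread evenly along X, gave mixed results: among peaks in the decile of highest signal value the X ratio was 1.94 (1.36 to 2.80), inside the autosomal range of 1.13 to 2.13 as such an offset predicts, and with a q under 0.05 it was 1.94 (1.68 to 2.25), above the highest autosome at 1.59. The share of replicate 1 X peaks with no other within 10 kb was 47.5% (45.7 to 49.3%). It lay inside the autosomal range of 10.6 to 57.2%, not above it as predicted for evenly spread calls, and below the 69.5% of random placement. Replicate 2, without the excess, was also below random placement, with 59.0% against 87.1%. The share covers all X peaks, so it cannot tell how the extra calls of replicate 1 were spread. A dosage offset could remain, whether it adds spread calls or lifts regions already marked, since the proportions of the sexes in each pool are not given in the sources used here. No biological explanation was tested.

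The peaks with the highest −log10 p outside chromosomes 18 and Y were named after their values were seen. A run of 3 peaks on chromosome 11 from 3184205 to 3200097, over Drg1 and Sfi1, had −log10 p of 128 to 147 with signals of 3.63 to 4.12. A pair on chromosome 17 from 39842974 to 39848898 had 105 and 121. Its nearest protein-coding gene was Esp38, over 100 kb away, and genes of other annotated types were not considered. Others lay in Cdk8, Gm10800, Gm10801, Tmem267 and Aida. Over these 10 peaks, the share of once-found words ran from 35.6% to 93.7%, and their signals ranked between the 4.21 and 95.4 percentiles of the replicated list. They were kept in the main comparisons, and whether they are artifacts was not tested. No list of regions prone to excess reads was used here to filter peaks.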
